A study of Mus musculus with 2 samples.

How the data were processed

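Single-cell RNA was measured in stromal cells of pancreatic tumours grown in mice with a p16-driven, inducible Cre and a tdTomato reporter. Per the labels, tumours of PBS-perfused mice were dissociated with enzymes, red cells were lysed, and antibody-stained cells were sorted into tdTomato positive and tdTomato negative fractions, each giving 1 library with the 10x Genomics 3' kit version 3.1. The deposited files hold counts of unique molecular identifiers (UMIs) per gene and barcode; per the file headers they were made with Cell Ranger 7.0.1, on mm10 per the submitters' processing notes. How barcodes were called as cells was not given in the sources used here, and the lowest barcode total was 500 UMIs. Both matrices hold 31054 features, tdTomato among them. Gene coordinates are from the GENCODE M21 annotation of mm10.

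The Tom positive library held 7568 barcodes with 128275546 UMIs, and the Tom negative library 13604 barcodes with 164646314 UMIs. Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs passed (4365 and 6677), and Scrublet, run per library in scanpy, removed 64 and 98 doublets. The minimum of 1000 UMIs alone excluded 2281 and 6285 barcodes. Kept were 4301 and 6579 cells with 91.4% and 91.7% of all UMIs, at median depths of 24178 and 20611 UMIs and 5016 and 4538 genes. For a gene at 0 counts in a group, a floor of 3 counts was used to give its ratio as a bound. That floor is 0.0256 and 0.0199 CPM over all kept cells. Medians were 40079 and 37448 UMIs in fibroblast-like cells, 18780 and 19980 in macrophage-like cells and 1171 and 1245 in mesothelial-like cells. The highest class median was 57074 UMIs, in Tom positive epithelial or carcinoma-like cells.

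Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was clustered by Leiden at resolution 1 into 26 clusters, without correction between libraries. Marker lists for 23 classes were written before the data were examined. A cluster took a class name when at least 3 of its markers reached 50 CPM, their mean log2 level over the median cluster was at least 1, and its 10 leading genes held no more markers of another class; these limits were set after the data were seen. Named this way were 12 classes, and 5 clusters stayed unnamed. Clusters 2, 3 and 18 were led by markers of another class than the best-scoring one, those of clusters 2 and 3 being of dendritic cells and monocytes, and clusters 13 and 20 had low UMI counts and no marker among their leading genes.

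Counts were summed per library over all kept cells and over each of 7 populations with at least 100 cells in both libraries, and scaled by the total of each sum to CPM. Differences are log2 of CPM plus 1, Tom positive minus Tom negative, and ratios are of plain CPM. Intervals at 95% are exact binomial for shares, Poisson for CPM, and exact conditional for ratios; as there was 1 library per group, they hold counting error only and no test between groups was run. Genes named in the text are among the 12 highest and 12 lowest log2 differences at 50 CPM or more over all cells and at 100 CPM or more in fibroblast-like and macrophage-like cells, 3 each way in the others, and up to 4 members of a list; some of these genes are not reported here but count in the totals. In a class, genes were passed over whose level was below 1/5 of that in another class of the same library, since free RNA of that class can carry them, and mitochondrial, ribosomal protein, haemoglobin and predicted genes and names given to more than 1 feature were not ranked.

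For 30 gene lists, members at 10 CPM or more in a library were measured, and their median log2 difference was placed among 10000 random lists matched on level in 20 bins, as a description and not a test. The names Macroh2a1, Ccn1 and Ccn2 had no match in the files. Erythrocyte genes were below 10 CPM over all cells, and fewer than 3 epithelial transcripts were measured in fibroblast-like or macrophage-like cells. For shares of cells with a transcript, cells were also thinned to 2000 UMIs, leaving out shallower ones. Reporter-high cells are those at 500 CPM of tdTomato or more, a level set after the data were seen. The calculation of folds, intervals and list medians was run on simulated sums of counts that varied by counting error only. Of 200 genes set 2-fold apart, 100% were past 1.5-fold among 8535 fibroblast genes and among 7991 macrophage genes. No unchanged gene was, and intervals held the true ratio for 94.7% and 95.9% of genes. Variation between cells, animals or libraries was not simulated, and filtering, clustering and naming were not part of it.

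Barcode sequences were compared between libraries, and a barcode was doubted when the other library held it with more than 5 times the UMIs, or when both held it with under 5000 UMIs. Alternatives tried were mitochondrial limits of 5% and 20%, minimums of 1000 genes with 3000 UMIs and of 200 genes alone, doublets kept, Leiden resolution 2, TMM factors (edgeR 4.0.16), median-of-ratios factors, totals without mitochondrial, ribosomal and haemoglobin genes, means over cells, thinned cells, a pseudocount of 5, list limits of 0 and 50 CPM, and populations weighted equally. Added after the data were seen were clusters weighted equally, reporter-high cells only, and leaving out doubted barcodes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used, with seed 1.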

Results

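Stromal cells of mouse pancreatic tumours were compared by a genetic reporter of p16 expression. In it, inducible Cre recombinase made from the p16 locus switches on tdTomato once induced. Cells sorted as tdTomato positive (Tom positive) and tdTomato negative (Tom negative) each gave 1 single-cell RNA-seq library, and both libraries were scored for cell classes, reporter level, Cdkn2a and gene lists. With 1 library per group no difference between groups was tested, and the 95% intervals below hold counting error only. Genes at least 1.5-fold apart are called higher or lower in the Tom positive library. After filtering, 4301 Tom positive and 6579 Tom negative cells were kept.

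Vascular cells made up more of the Tom positive sort, while fibroblasts, the main matrix producers of pancreatic tumours, filled a like share of both sorts. Endothelial-like cells, which line blood vessels, and lymphatic endothelial-like cells, which line lymph vessels, both took larger shares of the Tom positive library. Pericytes or smooth muscle cells, which wrap vessel walls, were less frequent there, while the order of the sorts for macrophage-like and neutrophil-like cells depended on the filters.

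Fibroblast-like cells were 35.9% (95% interval 34.4 to 37.3) of kept cells in the Tom positive sort and 38.0% (36.8 to 39.1) in the Tom negative sort. Macrophage-like cells were 14.9% (13.9 to 16.003) and 11.7% (10.97 to 12.5), a ratio of 1.27 that was 0.905 with minimums of 1000 genes and 3000 UMIs and 1.09 without doubted barcodes. Neutrophil-like cells were 6.72% and 8.21%, a ratio of 0.819 that was 1.29 with those minimums and 1.06 with a minimum of 200 genes and no UMI minimum. Endothelial-like cells stood at 10.7% (9.81 to 11.7) against 1.76% (1.46 to 2.11), a ratio of 6.08 (4.95 to 7.52), and lymphatic endothelial-like cells at 3.42% against 0.502%, a ratio of 6.81 (4.65 to 10.3). For pericytes or smooth muscle-like cells the shares were 1.07% and 2.43%, a ratio of 0.440 that was 0.718 with the 200-gene minimum, and for epithelial or carcinoma-like cells 0.674% and 0.654%. Mast-like cells numbered 31 and 2, T or NK-like cells 40 and 14, and skeletal muscle-like cells 16 and 0, where 0 of 6579 cells allows a share of up to 0.0561%. Mesothelial-like cells (3.98% and 10.97%) and plasma-like cells (0.628% and 1.41%) had low UMI counts, and 94.9% of their barcodes were present in both libraries, so their shares cannot be read as shares of either sort. Clusters left unnamed held 20.0% of Tom positive and 24.1% of Tom negative cells. Among them, cluster 2, led by Ccl17, Ccr7 and Ccl22, held 5.98% and 10.7%, and cluster 3, led by Chil3, F13a1 and Arg1, held 10.2% and 6.004%.

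In all, 3660 barcodes were present in both libraries, and many paired a deep cell of one sort with a shallow copy in the other. The endothelial ratio was 3.21 with a mitochondrial limit of 20% and 2.53 with a minimum of 200 genes and no UMI minimum. Of the 33 Tom negative lymphatic endothelial-like cells, 21 carried doubted barcodes, which the Tom positive library held with far more UMIs or both held with few, and the lymphatic ratio was 16.1 without doubted barcodes and 4.19 with the 200-gene minimum.

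**Figure D1:**
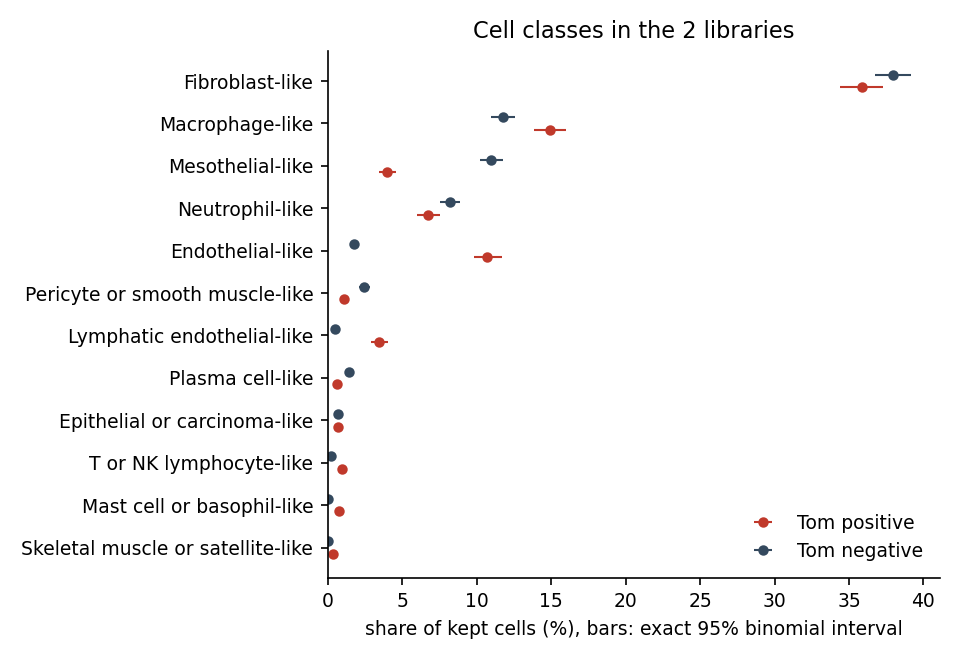
Share of kept cells (%) in each named class of the Tom positive and Tom negative libraries, with exact binomial 95% intervals as bars. Endothelial-like cells stood at 10.7% and 1.76%, and fibroblast-like cells at 35.9% and 38.0%.

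**Figure D2:**
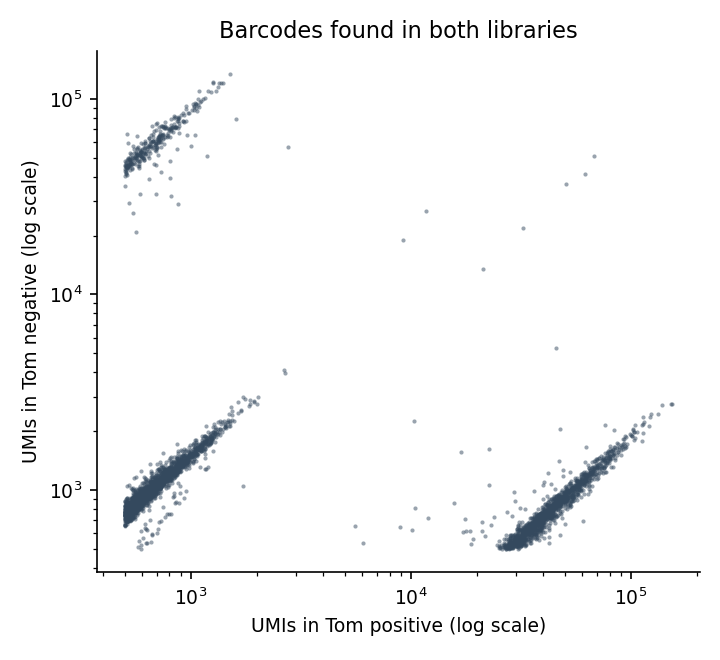
UMIs of the 3660 barcodes present in both libraries, Tom positive against Tom negative, on log scales. Most pairs were deep in only 1 library or shallow in both, with 1367 Tom positive cells paired to shallow Tom negative copies.

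Relative to all their UMIs, macrophages, neutrophils, monocyte-like cells and the few mast-like cells of the Tom positive sort held the most reporter transcript, whereas most sorted fibroblasts held little. Reporter UMIs per cell were not ranked, and Tom positive neutrophil-like cells were far shallower (median 3564 UMIs) than fibroblast-like ones (40079). The tdTomato transcript is made in cells that expressed Cre from the p16 locus during induction, and in their descendants. It was higher in the Tom positive library in most classes but not in mesothelial-like or plasma-like cells. Endothelial-like cells, despite their larger share, differed least in the reporter among vascular cells.

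Over all kept cells tdTomato was at 547 CPM in the Tom positive and 29.6 CPM in the Tom negative library, a ratio of 18.5 (17.9 to 19.1). The log2 difference of tdTomato, 4.16, was 3.13 with populations weighted equally, 3.32 with means over cells and 5.72 with reporter-high Tom positive cells only. Macrophage-like cells held 1209 and 48.9 CPM (ratio 24.7), neutrophil-like cells 1375 and 103 CPM (13.4), and fibroblast-like cells 407 and 16.9 CPM (24.0). Endothelial-like cells held 203 and 103 CPM, a ratio of 1.98 (1.75 to 2.24). Lymphatic endothelial-like cells held 601 and 105 CPM, cluster 2 held 732 and 37.2 CPM, and cluster 3 held 1097 and 53.7 CPM. Of the 33 Tom negative lymphatic cells, 21 carried doubted barcodes, so reads of Tom positive cells can be part of the 105 CPM. Mesothelial-like cells held 97.4 and 136 CPM (0.716, 0.439 to 1.12) and plasma-like cells 111 and 182 CPM (0.610, 0.185 to 1.58).

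At 500 CPM of tdTomato or more stood 74.1% (70.5 to 77.5) of Tom positive macrophage-like cells, 82.0% of cluster 3 and 63.4% of cluster 2. So did 71.0% (52.0 to 85.8) of the 31 Tom positive mast-like cells. Only 18.1% (16.2 to 20.1) of Tom positive fibroblast-like cells and 3.69% of endothelial-like cells reached that level. In the Tom negative sort it was reached by 3 fibroblast-like cells (0.120%) and 4 macrophage-like cells (0.518%). For neutrophil-like cells (64.0% and 5.37%) that level takes only 2 UMIs at their median depths of 3564 and 2744.5 UMIs; a tdTomato UMI was found in 76.5% and 17.8% of them, or 68.8% and 14.2% after thinning to 2000 UMIs (29 and 83 left out). Between 250 and 1000 CPM lay 99 of the 1542 Tom positive fibroblast-like cells, 156 of the 641 macrophage-like cells and 114 of the 461 endothelial-like cells. Within Tom positive fibroblasts the high level was most frequent in cluster 6, led by Dmkn, Sema3e and Wnt2 (81 of 187 cells), and in cluster 10, led by Stra6, Col7a1 and Tnc (85 of 247). It was rare in cluster 4, led by Fmod, Comp and Thbs4 (31 of 369), and in cluster 5, led by Hmcn2, C7 and Sfrp4 (18 of 339).

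At least 1 tdTomato UMI was found in 70.9% of Tom positive and 35.7% of Tom negative fibroblast-like cells, and in 93.3% and 48.8% of macrophage-like cells. Carcinoma-like cells, the nearest to a class without the reporter as the tumours were grafted, held such a UMI in 82.8% and 11.6% of cells at median depths of 57074 and 21761 UMIs. Of the 43 Tom negative ones, 15 carried doubted barcodes. Carcinoma-like cells carried Xist at 1228 and 1224 CPM, against at most 0.369 CPM in fibroblast-like or macrophage-like cells. Whether carcinoma-like cells lack the reporter was not tested. With each cell thinned to 2000 UMIs the shares became 24.97% and 3.62% for fibroblast-like cells (20 and 69 shallower cells left out), 77.2% and 11.7% for macrophage-like cells (6 and 10 left out), and 11.1% and 0% for carcinoma-like cells (2 and 14 left out).

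**Figure D3:**
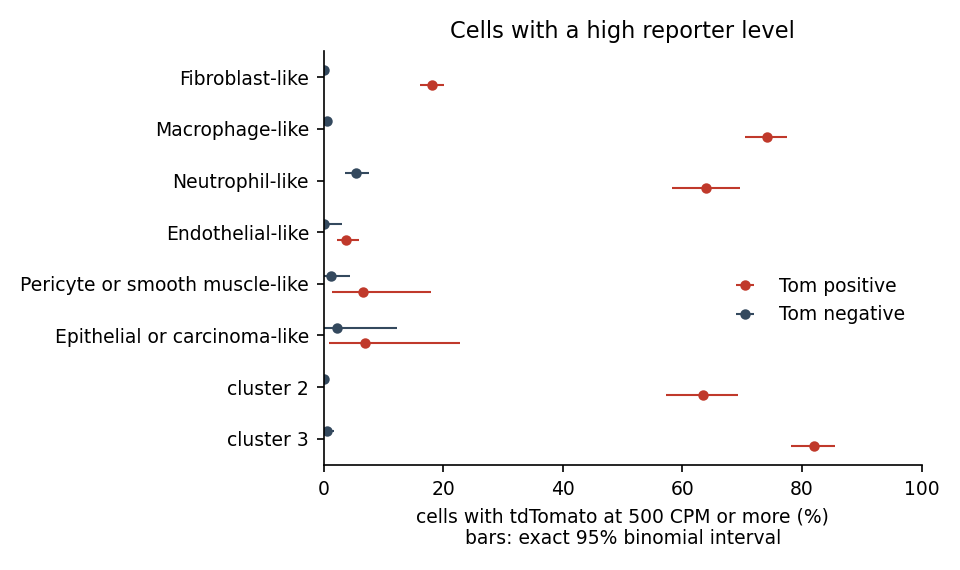
Share of cells (%) with tdTomato at 500 CPM or more in the larger classes and unnamed clusters of the Tom positive and Tom negative libraries, with exact binomial 95% intervals. Tom positive macrophage-like cells reached 74.1%, and fibroblast-like cells 18.1%.

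Macrophages and monocyte-like cells carried more Cdkn2a in the Tom positive sort, and fibroblasts carried as much in either sort. Cdkn2a encodes the cell cycle inhibitor p16Ink4a and, from another promoter, p19Arf. The gene lies on mm10 chromosome 4 (89274471 to 89294653, minus strand), and both transcripts end within 89274471 to 89274541, the part that a 3' assay reads, so they were counted together. Among macrophages the difference was largest in cluster 14, led by Nos2, Mmp12 and Hmox1.

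Cdkn2a stood at 24.2 CPM (23.3 to 25.1) over all Tom positive cells and at 18.97 CPM (18.3 to 19.7) over all Tom negative cells, a ratio of 1.28 (1.21 to 1.34). This log2 difference over all cells, 0.34, was 0.62 with means over cells and 1.10 with reporter-high Tom positive cells only, both past 1.5-fold. In macrophage-like cells Cdkn2a was at 57.2 and 27.3 CPM, a ratio of 2.09 (1.86 to 2.35). Cluster 14 held 151 and 56.9 CPM (2.65, 2.30 to 3.06). Cluster 9, the Cd163, Folr2 and Pf4 macrophages, held 22.9 and 15.6 CPM (1.47). Cluster 3 held 57.5 and 29.1 CPM (1.98, 1.68 to 2.32) and cluster 2 held 32.3 and 18.5 CPM (1.75, 1.45 to 2.10), but the log2 difference in cluster 2 was -0.66 once cells were thinned to 2000 UMIs. Neutrophil-like cells held 97.6 and 53.6 CPM (1.82, 1.35 to 2.47), but the median log2 difference over all their genes was 0.39, and Cdkn2a stood under 1.5-fold there with TMM factors.

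Fibroblast-like cells held Cdkn2a at 15.2 CPM (14.3 to 16.2) in the Tom positive and 16.5 CPM (15.7 to 17.3) in the Tom negative sort, a ratio of 0.924 (0.852 to 1.002). A Cdkn2a UMI was found in 32.9% and 31.9% of fibroblast-like cells, or 3.02% and 2.97% after thinning to 2000 UMIs, and in 37.1% and 25.5% of macrophage-like cells, or 8.19% and 4.59% after thinning. Carcinoma-like cells held a Cdkn2a UMI in 3.45% and 2.33% of cells at median depths of 57074 and 21761 UMIs. Endothelial-like cells held 8.91 and 13.6 CPM (0.654, 0.457 to 0.958), and lymphatic endothelial-like cells 33.0 and 13.2 CPM (2.51, 1.05 to 7.85). The Tom negative lymphatic value rests on 33 cells at a median of 1605 UMIs. As 21 of them carried doubted barcodes, that ratio cannot be read as one between the sorts.

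In macrophage-like cells the Cdkn2a log2 difference of 1.04 was 0.54 with a mitochondrial limit of 20%, 0.52 with a minimum of 200 genes and 0.50 with doublets kept, all under 1.5-fold.

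**Figure D4:**
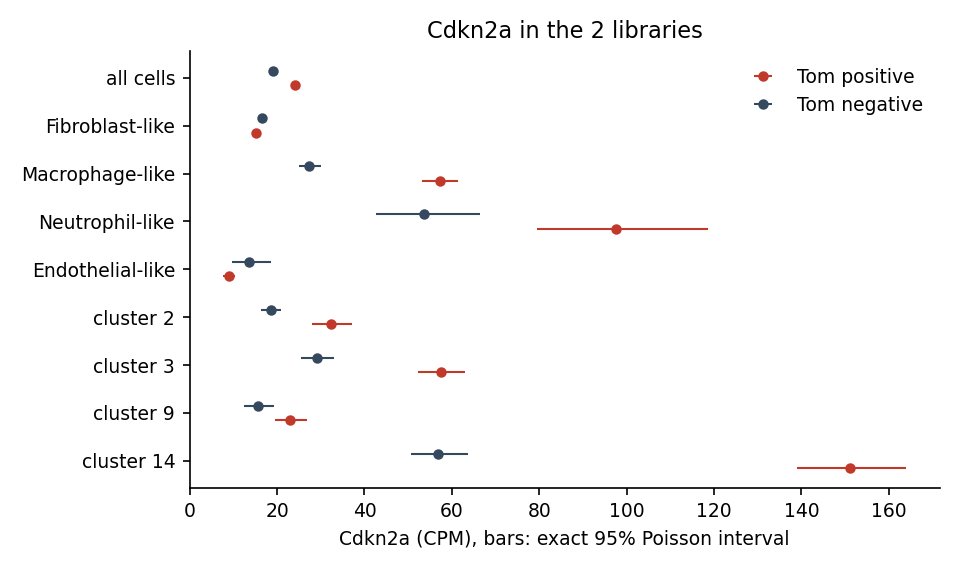
Cdkn2a (CPM of summed counts) in all kept cells, the larger classes and selected clusters of the Tom positive and Tom negative libraries, with Poisson 95% intervals. Cluster 14 macrophages held 151 and 56.9 CPM, and fibroblast-like cells 15.2 and 16.5 CPM.

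Summed over all kept cells, the Tom positive library held more transcripts of vascular and lymphatic endothelium and of mast cells, and fewer of several mural cell, chemokine and MHC class II genes. Selp, Ptprb and Cyyr1 are genes of blood vessel endothelium, Reln, Mmrn1 and Lyve1 of lymphatic endothelium, and Cma1 and Mcpt4 encode proteases of mast cell granules. On the lower side stood Rgs5 and Acta2 of mural cells, the chemokines Cxcl13 and Cxcl1, and H2-Aa, which encodes a chain of MHC class II.

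Among ranked genes at 50 CPM or more, Reln (72.2 and 2.99 CPM, ratio 24.1), Cma1 (51.6 and 2.19 CPM, 23.6) and Selp (83.0 and 3.94 CPM, 21.1) had the largest ratios. Besides tdTomato, Mmrn1 (18.9), Mcpt4 (17.7), Ptprb (11.1), Cyyr1 (10.4), Aqp1 (10.3), Lyve1 (10.2), Adgrl4 (9.42) and Prex2 (8.78) came next. Lower in the Tom positive library were the histone gene Hist1h2ap (18.6 and 93.3 CPM, 5.02-fold), Nme2 (3.41-fold), Cxcl13 (3.01-fold), Gstp1 (2.43-fold), Rgs5 (2.25-fold), Acta2 (2.07-fold), Cxcl1 (2.04-fold), H2-Aa (2.01-fold) and Ear2 (2.01-fold). Igkc (2.87-fold) and Ighm (2.58-fold) were lower too, but without doubted barcodes the log2 difference of Igkc was 0.25 in place of -1.51. Gstp1 shares much of its 3' sequence with other genes, which leaves its count uncertain.

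Of 20 measured angiogenesis and endothelium genes, 17 were higher, with a median log2 difference of 1.91 (1.05 to 2.56), above all 10000 matched random lists. Cdh5 (8.60-fold), Angpt2 (9.36-fold) and Vwf (9.04-fold) were among them. Sums over all cells hold the larger endothelial share of the Tom positive library. Within endothelial-like cells this list had a median of 0.04 (-0.25 to 0.38), with 4 of 20 higher and 2 lower. Basement membrane genes had a median of 0.25, with Lama5 5.24-fold and Col18a1 2.44-fold higher, and lipid handling genes 0.08, with Fabp4 4.76-fold and Cd36 3.07-fold higher. MHC class II presentation (median -0.69, 6 of 9 lower), secreted inflammatory factors of senescence (-0.39, 4 of 20 lower), inflammatory CAF genes (-0.33, 4 of 21 lower), and secreted growth factors and proteases of senescence (-0.23, 6 of 33 lower) stood below nearly all random lists. None of the 16 measured cell cycle inhibitor and senescence genes was past 1.5-fold, at a median of -0.12 (-0.28 to 0.07). With Tom positive cells at 500 CPM of tdTomato or more, the MHC class II median was 0.35 and the log2 difference of H2-Aa 0.10.

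Fibroblasts of the Tom positive sort held more transcripts of several fibrous matrix proteins and fewer of several chemokines. Thbs4, Fmod, Cilp and C1qtnf3 encode proteins of tendon-like and cartilage-like matrix, and Col11a1 a collagen of fibrillar networks. Ccl2, Cxcl1 and Cxcl13, which draw monocytes, neutrophils and B cells, stood lower, as did Nfkb1, which encodes a subunit of NF-kB, and Inhba, a ligand of the TGF-beta family. Most of these matrix genes were higher in the Tom positive fibroblasts with little reporter and not in those with much of it. These groups also differed in their mix of fibroblast clusters, which was not separated from reporter level.

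Thbs4 (mm10 chromosome 13, 92751590 to 92794818) was at 423 CPM in Tom positive and 139 CPM in Tom negative fibroblast-like cells, a ratio of 3.05 (2.99 to 3.11), and Fmod (chromosome 1, 134037254 to 134048277) at 100.4 and 36.2 CPM (2.78). Cilp (2.03), Ctla2a (1.93), Dpp6 (1.82), Apod (1.81), Itgbl1 (1.73), Smoc2 (1.72), Col11a1 (1.67), Podn (1.66) and C1qtnf3 (1.65) followed. Lower were Cxcl13 (42.5 and 105 CPM, 2.47-fold), Ccl2 (179 and 328 CPM, 1.83-fold), Cxcl1 (1.68-fold), Inhba (1.68-fold), Slc4a4 (1.65-fold), Htra3 (1.63-fold), Ugdh (1.60-fold), Sema3c (1.59-fold), Noct (1.58-fold), Nfkb1 (1.54-fold) and Abi1 (1.54-fold).

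At 500 CPM of tdTomato or more, Tom positive fibroblasts held Thbs4 at 93.5 CPM, against 495 CPM in those below that level and 139 CPM in the Tom negative sort. Fmod (24.6, 117 and 36.2 CPM) and Cilp (207, 614 and 265 CPM) had the same order, whereas Ctla2a was higher at either level of reporter (428, 457 and 235 CPM). Cxcl1 (842, 460 and 890 CPM), Nfkb1 (855, 414 and 763 CPM) and Ugdh (539, 258 and 494 CPM) were low only where the reporter was low. Of the 11 higher genes other than tdTomato, 7 lay on the other side in the reporter-high cells. Clusters 4, 5 and 7 held 23.9%, 22.0% and 21.8% of Tom positive fibroblasts and 17.1%, 13.5% and 15.7% of Tom negative ones. Clusters 6 and 10 held 12.1% and 16.02% against 25.2% and 22.99%. Of the reporter-high Tom positive fibroblasts, clusters 6 and 10 held 29.0% and 30.5%, and cluster 4, led by Fmod, Comp and Thbs4, held 11.1%. The mix of clusters was thus not separated from reporter level.

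**Figure D5:**
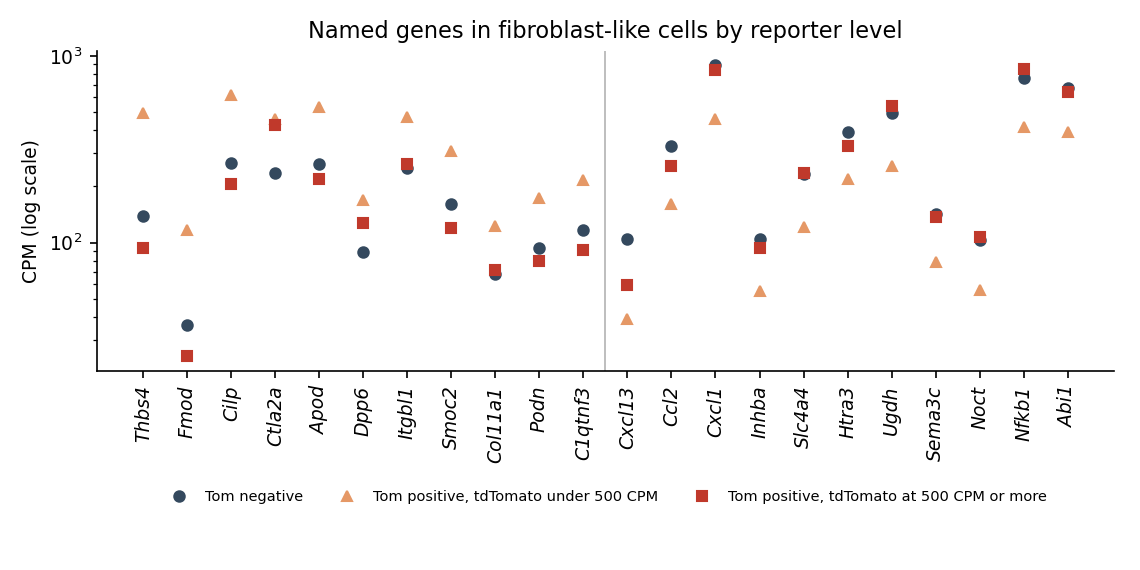
Named fibroblast genes (CPM of summed counts, log scale) in Tom negative fibroblast-like cells and in Tom positive ones under 500 CPM and at 500 CPM or more of tdTomato; a vertical line parts the higher from the lower genes. Thbs4 stood at 139, 495 and 93.5 CPM in these groups.

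Of 18 inflammatory factors that senescent cells secrete, 6 were lower and 2 higher in Tom positive fibroblasts, with a median log2 difference of -0.47 (-0.87 to -0.15), below every matched random list. Il1b (3.04-fold), Ccl3 (2.23-fold), Cxcl2 (2.14-fold) and Ccl4 (2.14-fold) were lower, and Ccl8 (1.61-fold) and Cxcl5 (1.52-fold) higher. The macrophage transcript C1qa (7.30 and 15.4 CPM) and the neutrophil transcript S100a8 (3.32 and 18.99 CPM) were lower in the same fibroblasts, so free RNA of immune cells was not separated from expression of these factors or of MHC class II. Secreted growth factors and proteases of senescence had a median of -0.21, with Mmp9 2.07-fold, Mmp12 2.05-fold and Mmp10 1.60-fold lower, and NF-kB response genes one of -0.19 (4 of 18 lower), which was 0.01 in reporter-high cells. Inflammatory CAF genes stood at -0.21 (4 of 21 lower, with Has2 and Efemp1 each 1.59-fold lower), and myofibroblastic CAF genes at -0.02, although Acta2 was 1.58-fold lower. Collagens and matrix genes had a median of 0.18 (0.07 to 0.25), above every random list, although only Col11a1 of 25 was past 1.5-fold, and Col12a1 and Lum had ratios of 1.41 and Eln of 1.38. That median was 0.07 in reporter-high and 0.23 in reporter-low cells.

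Hypoxia and glycolysis genes had a median of -0.36 (-0.44 to -0.27) in Tom positive fibroblasts, with 1 of 27, Ero1l (1.54-fold), lower and none higher. That median was 0.26 in reporter-high and -0.53 in reporter-low cells. Proliferation genes stood at -0.38 (-0.66 to -0.24), with Cdc20 1.75-fold and Ccnb1 1.70-fold lower, and at -0.17 with the fibroblast clusters weighted equally. DNA replication genes stood at -0.22, which was -0.51 in reporter-high and -0.17 in reporter-low cells. MHC class II genes had a median of -1.33 (-1.67 to -0.74), which was -0.47 in reporter-high cells, led by H2-Aa (10.1 and 34.5 CPM, 3.41-fold) and Cd74 (20.4 and 54.8 CPM, 2.68-fold). Antigen-presenting CAF genes stood at -1.04, with Saa3 2.23-fold higher, and at -0.10 in reporter-high cells and 0.09 for members at 50 CPM or more.

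In fibroblast-like cells none of 15 cell cycle inhibitor and senescence genes was past 1.5-fold (median -0.11, and 0.08 in reporter-high cells), and Cdkn1a was at 46.3 and 59.8 CPM. Medians stood at -0.19 for interferon response and for tumour-associated macrophage polarization (0.21 in reporter-high cells), -0.28 for angiogenesis and endothelium (0.18 in reporter-high cells), -0.17 for lipid handling (0.05 in reporter-high cells), -0.14 for immediate early genes, and -0.41 for neutrophil transcripts. MHC class I presentation and the unfolded protein response (each -0.10) and complement and apoptosis regulation (each -0.07) had medians near 0. So had immune checkpoints and TGF-beta response (each -0.06), oxidative stress response (-0.03), basement membrane (0.04) and lysosome and phagocytosis (0.06). Complement genes, with 3 of 11 lower and none higher, stood at -0.36 in reporter-high and 0.04 in reporter-low cells.

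Macrophages of the Tom positive sort held more Ccl8, Stab1, Pf4 and Maf and fewer transcripts of several MHC class II genes. Stab1 encodes a scavenger receptor, Maf a transcription factor of macrophages, and Ccl8 and Pf4 encode chemokines. H2-Aa, H2-Eb1 and Cd74 encode the MHC class II complex and its chaperone, and Retnla, Ear2 and Mgl2 mark monocyte-derived cells under type 2 cytokines.

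Ccl8 (mm10 chromosome 11, 82115185 to 82116799) was at 278 and 72.8 CPM in Tom positive and Tom negative macrophage-like cells, a ratio of 3.82 (3.58 to 4.07), but its log2 difference of 1.92 was 0.40 with a mitochondrial limit of 5%. Stab1 (248 and 134 CPM, 1.85), Pf4 (1.80), Frmd4b (1.78), F13a1 (1.73), Maf (1.73), Apoe (5516 and 3223 CPM, 1.71), Wfdc17 (1.69), Fcgrt (1.69) and Fkbp5 (1.68) were higher as well. Lower were Hist1h2ap (37.6 and 239 CPM, 6.35-fold), Retnla (219 and 415 CPM, 1.90-fold), Fgf13 (1.86-fold), Il1r2 (1.79-fold), H2-Eb1 (1.78-fold), Ear2 (1.73-fold), H2-Aa (891 and 1533 CPM, 1.72-fold), Plxdc2 (1.68-fold), Mgl2 (1.67-fold), Cd74 (1.66-fold) and Lpl (1.61-fold). With clusters 9 and 14 weighted equally, log2 differences turned for Apoe (-0.13), Frmd4b (-0.37) and Lpl (0.09). With the 200-gene minimum that of Il1r2 was 0.017 in place of -0.84. Cluster 9 held 59.3% of Tom positive and 42.5% of Tom negative macrophages, the cycling cluster 15 held 7.33% and 13.3%, and cluster 17, led by Retnla and Ear2, held 5.77% and 11.8%.

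Tumour-associated macrophage polarization, with 7 of 20 genes higher and 3 lower in Tom positive macrophages, had a median of 0.32 (-0.09 to 0.68), with Cd163 2.41-fold and Lyve1 2.14-fold higher and Ccl17 2.63-fold lower. Lysosome and phagocytosis stood at 0.18 (0.04 to 0.35), above every random list, although only Gpnmb (1.55-fold) of 22 was higher, and Grn and Ctsb had ratios of 1.33 and 1.32. Complement genes stood at 0.19, with C4b 1.90-fold higher, lipid handling at 0.18, and secreted inflammatory factors of senescence at 0.10. MHC class II presentation had a median of -0.50 (-0.78 to 0.06), proliferation -0.41 (-0.52 to -0.37, 2 of 20 lower) and DNA replication -0.34 (-0.45 to -0.23), with Rrm2 1.65-fold and Ccnb1 1.63-fold lower. Proliferation stood at -0.06 with clusters 9 and 14 weighted equally. That leaves out the cycling cluster 15, so it does not show the effect of weighting alone. Interferon response was at -0.20, with Cxcl9 5.60-fold, Gbp2 2.38-fold and Isg15 1.65-fold lower.

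Cdkn2a was the only higher gene among 15 cell cycle inhibitor and senescence genes in macrophage-like cells, where Hmga1 (1.59-fold) and Gadd45b (1.52-fold) were lower and the median was -0.13. Gas6 (1.82-fold) and Timp2 (1.58-fold) were higher among secreted growth factors and proteases of senescence, whose median was -0.07. Lists of mostly fibroblast transcripts had medians in macrophage-like cells of -0.40 for collagens and matrix (5 of 21 lower), -0.27 for myofibroblastic CAF (4 of 13 lower) and -0.39 for inflammatory CAF genes (2 of 17 lower). Antigen-presenting CAF genes stood at -0.66, where the 4 lower members, H2-Eb1, H2-Aa, Cd74 and H2-Ab1, are MHC class II genes of the macrophages themselves. The medians of basement membrane (-0.15), T cell markers and hypoxia and glycolysis (each -0.12), NF-kB response (-0.09), TGF-beta response (-0.08), apoptosis regulation (-0.06), MHC class I presentation (0.01), unfolded protein response (0.01), immediate early genes (0.04), oxidative stress response and immune checkpoints (each 0.06), angiogenesis (0.18) and neutrophil transcripts (0.44) were the rest.

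Endothelial cells of the Tom positive sort held fewer transcripts of the cell cycle than those of the Tom negative sort, and more of some interferon-induced GTPases. Ptn, a heparin-binding growth factor, was lower, and Tagln, an actin-binding protein, was higher. Fam155a (117 and 35.1 CPM, ratio 3.33), Pcdh7 (246 and 75.9 CPM, 3.24) and Tagln (221 and 70.2 CPM, 3.14) were higher in Tom positive endothelial-like cells, and Hist1h2ap (10.1-fold) and Ptn (15.9 and 156 CPM, 9.82-fold) were lower. All 19 measured proliferation genes were lower (median -1.12), with Cdk1 3.02-fold and Top2a 2.70-fold lower, and DNA replication genes stood at -0.85. Interferon response was at 0.38 (7 of 18 higher), with Gbp5 3.02-fold and Iigp1 1.99-fold higher, and NF-kB response at 0.39. Immediate early and dissociation stress genes stood at 0.33 in the same cells (6 of 20 higher), so handling stress was not separated from these differences. Macrophage transcripts such as Cd74 (14.1 and 259.7 CPM), C1qb (9.63 and 64.8 CPM) and Lyz2 (40.7 and 156 CPM) stood higher in the 116 Tom negative endothelial-like cells, so these cells were not free of macrophage RNA. Lists of mostly fibroblast transcripts were lower in the Tom positive ones. Inflammatory CAF genes stood at -0.87 (10 of 18 lower, 1 higher) and collagens and matrix at -0.42 (10 of 23 lower, 2 higher). Fibroblast RNA was thus not separated either.

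Neutrophils of the Tom positive sort held fewer transcripts of some interferon-induced genes, and more of Tex14, a gene of germ cell bridges. Tex14 (535 and 105 CPM, ratio 5.09) and Abca13 (104.3 and 21.9 CPM, 4.76) were higher in neutrophil-like cells, and Gdf15 (6.76 and 158 CPM, 23.4-fold) and Rsad2 (3.76-fold) were lower. Interferon response genes had a median of -0.51, with 6 of 14 lower and none higher. Tumour-associated macrophage polarization (-0.78, 9 of 15 lower) and complement (-0.37, 5 of 12 lower) were lower alongside, so macrophage RNA was not separated from expression in neutrophils. The median over all neutrophil genes was 0.39 and only 0.03 after TMM scaling, so neutrophil differences hold that shift.

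Cells of the unnamed cluster 2 held more Mmp9 (716 and 379 CPM, 1.89) and Ccl24 (1.57) in the Tom positive sort, and less Nfkbiz (1.59-fold). NF-kB response genes there had a median of -0.35, with Cxcl1 2.60-fold and Nfkbia 1.78-fold lower, and Ccl5 was 12.7-fold lower. Ccr7, among the leading genes of cluster 2, was itself at 20.3 and 102 CPM, and T cell markers stood at -1.61 (3 of 4 lower). A different mix of cells in cluster 2 was thus not separated from changed expression. Monocyte-type cells of cluster 3 held more Sema3c (293 and 128 CPM, 2.29), Mt2 (2.11), Retnla (6.38-fold) and Maf (2.12-fold), and less Lepr (2.26-fold) and Axl (1.90-fold). DNA replication genes in cluster 3 stood at -0.58 and MHC class II presentation at -0.40. Genes of mesothelial-like cells are not reported here, since most of their barcodes were present in both libraries.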

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

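Of the tests in this part, the one on sequence shared with other genes was written before its result was seen, and all others were chosen after seeing the results.

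The results flagged here are signals in data not used in the comparisons: tdTomato in barcodes left out for their depth, and barcode sequences. Tom negative barcodes under 1000 UMIs held tdTomato at 155 CPM and Tom positive ones at 194 CPM, against 29.6 CPM in kept Tom negative cells. Barcodes found in both libraries numbered 3660, or 48.4% of Tom positive and 26.9% of Tom negative barcodes, where 40.4 were expected from the rate among barcodes with at least 5000 UMIs in both. Some of these are inside the comparisons, since 233 Tom positive and 1234 Tom negative kept cells carried doubted barcodes.

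Chance sharing does not account for these barcodes, since 3660 is 90.5 times the expectation. For 1367 of them a Tom positive cell (median 41989 UMIs) had a low copy in the Tom negative library (median 767 UMIs), and 100% of 300 such copies correlated better with their own cell than with another, with tdTomato 12.96 times that of kept Tom negative cells with unshared barcodes. This is consistent with reads of Tom positive cells assigned to the Tom negative library, and 303 Tom negative cells had low copies in the other direction. A further 1979 barcodes had under 5000 UMIs in both libraries and held Igkc at 40796.5 and 40411.3 CPM in sum, and 94.9% (93.3 to 96.1) of mesothelial-like and plasma-like barcodes were shared, so separate capture of these cells in each library is not in line with the data. Where these cells came from stays open, and no biological explanation was tested.

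Gm10076 and Gstp1 were lower in the Tom positive library in each of 6 populations (log2 -2.01 to -1.48 and -1.31 to -0.89). Among low copies, those of Tom positive cells still held less than those of Tom negative cells. The ratios were 0.248 (0.208 to 0.298) and 0.185 (0.065 to 0.527), the latter from 9 and 9 UMIs. A difference in sequencing or read assignment after indexing thus does not account for it. Of 50-base words near their 3' ends, 62.9% and 53.0% occur in other genes, against 9 of 300 background genes at 50% or more. This met the limit of 50% set beforehand for reads shared with near-identical transcripts, but it does not show why the libraries differ. The cause of the difference stays open, and animal differences were not tested.

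Cdkn2a was not higher in Tom positive fibroblasts, although p16 drives the reporter. For Tom positive fibroblasts at 500 CPM of tdTomato or more the ratio was 1.15 (0.994 to 1.33). Over the whole class, dilution by reporter-low fibroblasts thus does not hide a rise of 1.5-fold. A smaller rise hidden by dilution stays open, as the log2 difference was 0.19 in reporter-high cells and -0.11 in all. Within clusters the reporter-high ratio ran from 0.755 (0.320 to 1.52) in cluster 19 to 1.52 (0.594 to 3.28) in cluster 5. It was 1.64 (1.08 to 2.42) in cluster 7, and within these clusters dilution of a 1.5-fold rise stays open. Different fibroblast clusters in the 2 libraries do not hide a 1.5-fold rise either, with a ratio of 1.02 (0.916 to 1.13) when clusters weighed the same. Within single clusters, over all their Tom positive cells, it was 0.833 to 1.15. As the Cre was inducible, the reporter marks past expression during induction in a cell or its ancestors. Whether these fibroblasts had silenced Cdkn2a was not tested.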

How the results depend on the processing

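The tests of reporter-high cells, equal cluster weights and doubted barcodes were chosen after seeing the results. No paired analysis was possible because each group had 1 library. Depth limits the low-UMI classes most, since thinning to 2000 UMIs leaves out most mesothelial-like and plasma-like cells. Of 1426 values of named genes past 1.5-fold, 1404 kept their direction. So did 112 of 118 such values of gene lists and 39 of 40 of class shares. The list values cover all cells, fibroblast-like cells and macrophage-like cells only. List medians of endothelial-like cells, neutrophil-like cells and the unnamed clusters were not run under the alternatives, so their dependence on processing was not tested. Of results treated as central and past 1.5-fold, 30 of 30 gene values, 16 of 16 list values and 7 of 7 share values kept their direction, counting direction only. The gene values were those of macrophage Cdkn2a and of tdTomato over all cells, the reporter on which cells were sorted. The list values were those of MHC class II in fibroblasts, and the share values those of endothelial-like cells. With central results under 1.5-fold included, 57 of 60 gene values, 117 of 117 list values and 20 of 21 share values kept their direction. Macrophage Cdkn2a was under 1.5-fold with the mitochondrial limit of 20%, the 200-gene minimum and doublets kept. For the values below, given as log2 differences with the starting value in brackets, the cause was not tested.

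With Tom positive cells at 500 CPM of tdTomato or more, fibroblast-like cells held Apod -0.27 (0.86), C1qtnf3 -0.35 (0.72), Cilp -0.36 (1.02), Fmod -0.54 (1.45), Podn -0.24 (0.72), Smoc2 -0.42 (0.78), Thbs4 -0.56 (1.60), Nfkb1 0.16 (-0.63), Noct 0.049 (-0.65), Slc4a4 0.015 (-0.72), Ugdh 0.13 (-0.68), Cdkn2a 0.19 (-0.11) and MHC class II -0.47 (-1.33). Over all cells this gave Ear2 0.19 (-0.98), H2-Aa 0.10 (-1.005), MHC class II 0.35 (-0.69), antigen-presenting CAF 0.10 (-0.61), epithelial -0.57 (0.98), neutrophil 0.089 (-0.66), Cdkn2a 1.10 (0.34) and tdTomato 5.72 (4.16), and macrophage proliferation -0.32 (-0.41).

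With clusters weighted equally, fibroblast-like cells held Cdkn2a 0.018 and proliferation -0.17 (-0.38). Among macrophage clusters only 9 and 14 had at least 50 cells in both libraries, so the cycling cluster 15 and cluster 17 were left out. With clusters 9 and 14 weighted equally, macrophage-like cells held Apoe -0.13 (0.77), Frmd4b -0.37 (0.83), Lpl 0.09 (-0.68) and proliferation -0.056. With populations weighted equally, Igkc was 0.20 (-1.51), Cdkn2a 0.45 and tdTomato 3.13 over all cells. Thinned cells gave Cdkn2a 0.020 in fibroblasts, 0.52 over all cells and -0.66 in cluster 2 (0.77), and tdTomato 3.90. Means over cells gave Cdkn2a 0.62 over all cells and 0.88 in macrophages (1.04), tdTomato 3.32 and epithelial -0.48. A pseudocount of 5 gave macrophage proliferation -0.36 and tdTomato 4.00, TMM and median-of-ratios factors each tdTomato 4.14, and list members at 50 CPM or more fibroblast antigen-presenting CAF 0.091 (-1.04).

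A mitochondrial limit of 5% gave Kcnk5 -0.084 in mesothelial-like cells (3.36) and macrophage proliferation -0.73. A limit of 20% gave macrophage Cdkn2a 0.54 and proliferation -0.29, tdTomato 4.14, and share ratios of 3.21 for endothelial (6.08) and 1.14 for macrophage-like cells (1.27). The 1000-gene minimum gave Igkc 0.30, macrophage proliferation -0.25, tdTomato 4.26, and share ratios of 0.804 for fibroblast (0.945) and 0.905 for macrophage-like cells. The 200-gene minimum gave Il1r2 0.017 in macrophages (-0.84), macrophage Cdkn2a 0.52, fibroblast MHC class II -1.68, tdTomato 4.01, and share ratios of 2.53 for endothelial, 0.773 for fibroblast, 1.10 for macrophage and 1.47 for plasma-like cells (0.444). Doublets kept gave macrophage Cdkn2a 0.50 and an endothelial ratio of 3.38. Leiden resolution 2 gave macrophage proliferation -0.29 and a fibroblast ratio of 0.836. Without doubted barcodes Igkc was 0.25, and share ratios were 0.824 for fibroblast and 1.09 for macrophage-like cells.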

Other observations

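The tests of this part were chosen after seeing the results.

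Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 387 CPM in Tom positive and 441 CPM in Tom negative macrophage-like cells, at 154 and 185 CPM over all cells, and at 46.3 and 59.8 CPM in fibroblast-like cells. Cdkn2b, the neighbour of Cdkn2a, stood at 6.02 and 7.16 CPM in fibroblast-like cells, and at 2.29 and 1.30 CPM in macrophage-like cells, a ratio of 1.76 (0.986 to 3.19). Among 460 named or list genes, only those at 50 CPM or more in both fibroblast-like and macrophage-like cells were compared. Of these, 0 were past 1.5-fold in opposite directions, and genes below that level, such as Cdkn2a, were not covered.

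Ltbp1, which encodes a protein that holds latent TGF-beta in the matrix, was at 53.9 and 97.3 CPM in Tom positive and Tom negative fibroblast-like cells, 1.81-fold lower. The matrix glycoprotein Spp1 was at 3632 and 5430 CPM there, a ratio of 0.669. Over all cells the gastric mucin partner Tff1 was at 23.4 and 0.980 CPM, 23.9-fold higher, and epithelial transcripts had a median log2 difference of 0.98, which was -0.48 with means over cells and -0.57 in reporter-high cells. Carcinoma-like cells numbered only 29 and 43, at median depths of 57074 and 21761 UMIs.

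Over all cells the remaining lists had median log2 differences of 0.14 for MHC class I presentation, 0.10 for tumour-associated macrophage polarization, 0.05 for apoptosis regulation, -0.03 for immune checkpoints, -0.06 for lysosome and phagocytosis, -0.07 for immediate early genes, -0.09 for oxidative stress response, -0.11 for collagens and matrix, -0.14 for complement, -0.16 for TGF-beta response, -0.19 for unfolded protein response and DNA replication, -0.20 for myofibroblastic CAF genes, -0.22 for NF-kB response, -0.24 for hypoxia and glycolysis, -0.25 for proliferation, -0.29 for interferon response, -0.49 for T cell markers, -0.61 for antigen-presenting CAF genes and -0.66 for neutrophil transcripts.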
